A study of Mus musculus with 18 samples.

How the data were processed

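Total RNA from the oculomotor nucleus and the cervical spinal cord of mice was hybridised as biotin-labelled cRNA to Affymetrix Mouse Expression Set 430A arrays, per the labels. The 18 arrays fall into 6 groups of 3: each region from mutant mice of 6 weeks, control mice of 10 weeks and mutant mice of 10 weeks. The deposited values are intensity signals that the authors computed with Affymetrix Microarray Suite 5.0 and scaled per array; the 2% trimmed mean of each array used lay between 500.13 and 500.16, and all values were on a linear scale. The labels state neither the pooling of animals, the strain nor the mutation.

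The table held 22690 probe sets. After removal of 64 control probe sets, 25.0 (5% of the trimmed mean) was added to each signal, and log2 was taken with no further normalization. The 40% of probe sets with the lowest mean log2 signal were left out (limit 7.38), which left 13575 for testing. Symbols came from the array's probe annotation and were updated through gene identifiers for 20351 probe sets; 20380 had 1 symbol, 691 several and 1555 none, and genes with no name there were not analysed here. The gene table is for mouse assembly GRCm38.p6, which was used for names only. The tested probe sets with 1 symbol covered 8072 genes.

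A mean for each of the 6 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend on signal; 11 residual degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method within each of 10 contrasts. These were the regional difference in each of the 3 conditions and their mean, the genotype difference at 10 weeks in each region, their mean and their difference, and the change from 6 to 10 weeks in mutants of each region. A probe set with an adjusted p under 0.05 is called. For 42 lists of marker and pathway genes, each gene represented by its probe set with the highest mean signal, limma's camera was run with a preset correlation of 0.01 and again with an estimated one, adjusted over the 42 lists within a contrast. Separation of arrays was counted for contrasts of 2 groups. The groups, contrasts, tests, lists, the rule for naming genes and the alternatives, except for those named below as added, were set before the data were examined. The fit was planned with 18 arrays. Control spinal cord replicate 1 was left out after the values were seen, since its signals were not tied to the probe sets of their positions, so that its group held 2 arrays.

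Genes were named by a rule. In each contrast, among called probe sets with a change of at least 2-fold, 1 symbol and (for 2 groups) separated arrays, the 8 genes with the largest change in each direction were eligible. A change against a group whose mean signal lay below the offset has a size that depends on the offset, so such genes have no firm place in that order. Where fewer than 5 passed, the 5 with the smallest p in each direction are given as values. Up to 4 members of each list with the smallest p were also eligible, and Sod1 is given in every contrast. Each value is that of 1 probe set, and other probe sets of a gene did not always move alike.

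The alternatives were quantile normalization, median centring, values floored at the offset, an offset 4 times larger, no filter, a filter of 60%, eBayes without a trend, a fit of the arrays of a contrast alone, a replicate block, 1 probe set per gene, a rule of the submitters' kind (every pairwise comparison in 1 direction and a mean change over 2-fold), the 2-fold threshold and leaving out each array. A fit of all 18 arrays and a fit without both arrays with high pituitary hormone signals were added after seeing the data. The submitters' present and absent calls need probe-level data and were not computed.

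The steps were tested on simulated data with 200 of 13575 probe sets changed in each of 20 runs per contrast. Of 2-fold changes, 92.6% were called for the regional difference at 6 weeks, 92.3% for genotype in the oculomotor nucleus, 86.3% for genotype in spinal cord and 67.2% for the genotype by region difference; of 1.41-fold changes, 42.9%, 41.6%, 33.4% and 10.6%. False calls made up 4.58% to 5.18% of the calls. A list shifted by 0.3 in spinal cord was called in 20 of 20 runs, also with an estimated correlation, and 0 of 800 unshifted lists were called. The simulated probe sets varied independently of each other. These runs therefore do not show how the set test behaves for genes that vary together, as list members can in the real data.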

Results

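RNA from 2 motor regions of mice was measured on oligonucleotide arrays: the oculomotor nucleus, which moves the eyes and is spared in amyotrophic lateral sclerosis (ALS), and the cervical spinal cord, which is affected. Each region was taken from mice of an ALS model at 6 and at 10 weeks of age and from control mice at 10 weeks, with 3 arrays in each of the 6 groups. The labels name no mutation, and no control of 6 weeks was measured. Control spinal cord replicate 1 was left out, because across probe sets its correlation with the other arrays lay between 0.0104 and 0.0143, which left 17 arrays and 2 in that group. Between the 17 arrays the correlation across probe sets ran from 0.957 to 0.985, and their median signals ran from 207 to 226. The labels do not say whether each array stands for a separate animal, so p-values measure only the spread between these samples, and the number of arrays limits the precision. Below, log2 fold changes carry their standard error (SE), "called" means an adjusted p under 0.05 in limma over 13575 probe sets, and n is 3 arrays per group, or 2 for control spinal cord.

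Tissue was the largest source of difference among the arrays. The first principal component carried 42.7% of the variance and placed the oculomotor arrays between -23.5 and -16.0 and the spinal cord arrays between 19.3 and 26.9. On the second, with 10.9%, the 3 control oculomotor arrays lay between -18.1 and -16.3 and the 6 mutant oculomotor arrays between 3.29 and 18.6. In spinal cord the groups lay closer there, with controls at -5.69 and -16.3 and mutants between -4.46 and 6.82.

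**Figure D1:**
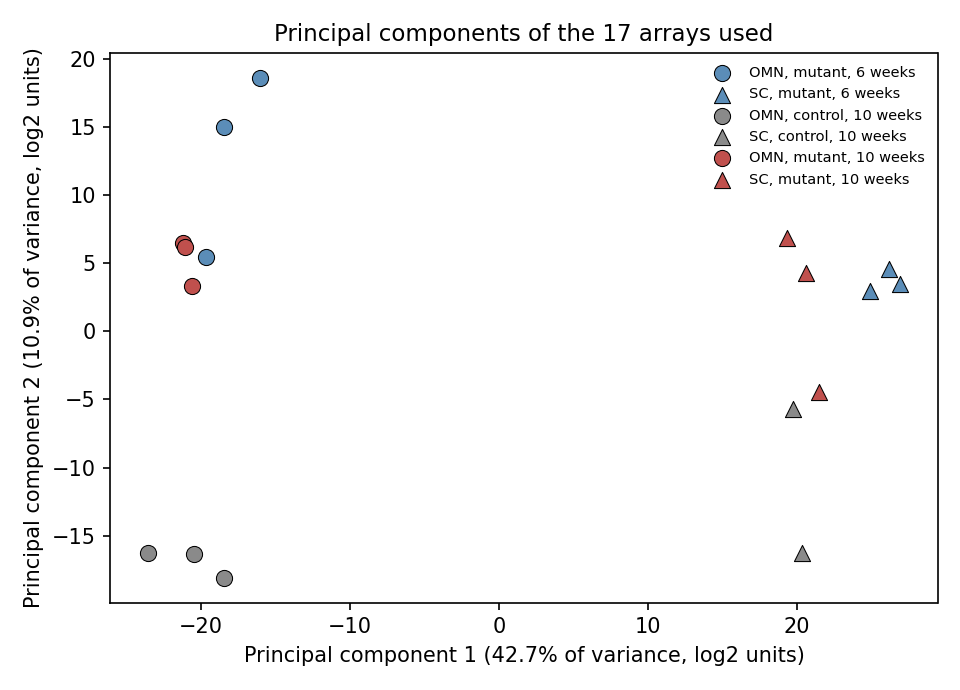
Each of the 17 arrays by its scores on the first principal component (42.7% of variance, x axis) and the second (10.9%, y axis), with the region as the shape and the group as the colour. The regions part along x, and the 3 control oculomotor arrays lie between -18.1 and -16.3 on y.

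In mutant mice of 6 weeks, the oculomotor samples had higher signals than spinal cord for genes of monoamine neurons and lower ones for Hox genes. The dopamine transporter Slc6a3 was higher by a log2 fold change of 3.66 ± 0.17 (12.6-fold). The serotonin transporter Slc6a4 was higher too (adjusted p = 3.50e-12), but its mean signal in spinal cord lay below the offset added to every signal, so the size of its change depends on that offset (4.73, or 3.20 with an offset 4 times larger). The same holds for Hoxc8, which marks position along the body axis and was near background in the oculomotor nucleus (-5.19, or -3.87 with the larger offset). All 8 measured members of the spinal Hox list were lower. Genes of motor neurons were lower in the oculomotor samples too: Slc18a3, which loads acetylcholine into vesicles, had -2.10 ± 0.13 and Chodl, a gene of fast motor neurons, -2.96 ± 0.20. This comparison asks how the spared region differs from the affected one at the earlier age.

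Other large rises were Th, the first enzyme of dopamine synthesis (3.05 ± 0.13), Ddc, which makes dopamine and serotonin (2.86 ± 0.15), the transcription factor Tcf7l2 (2.80 ± 0.18), the neuropeptide gene Cartpt (2.01 ± 0.15), the noncoding RNA Rian (1.96 ± 0.20, with another of its 3 probe sets at 0.24 and not called) and the amino acid transporter Slc7a3 (1.90 ± 0.16). The other large falls were Hoxb5 (-4.34, or -3.09 with the larger offset, from a mean signal below the offset in the oculomotor nucleus), Hoxa5 (-3.99 ± 0.36), Hoxd8 (-3.73 ± 0.16), the apelin receptor Aplnr (-3.67 ± 0.19), the protease inhibitor gene Serpinb1b (-3.65 ± 0.22), Hoxb6 (-3.41 ± 0.22) and the neurokinin B gene Tac2 (-3.07 ± 0.33). In all, 3239 probe sets of 2398 genes were called, 1656 higher and 1583 lower in the oculomotor nucleus. With median centring the split was 1251 higher and 1897 lower. Of the 338 called with at least a 2-fold change, 131 were higher and 207 lower. In the largest changes named here every array of one region lay above every array of the other. The rule for naming genes required this separation, so it is no further support for them. Chance gives it to 10% of probe sets for 3 against 3.

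Among the gene lists, 21 of 42 passed the set test at 6 weeks, 7 higher and 14 lower in the oculomotor nucleus, and 14 of them also with an estimated correlation. The dopaminergic list had a median of 1.50 (adjusted p = 4.69e-14), with 10 of its 11 measured genes called higher and 10 adjusted over the list alone. The serotonergic list had a median of 0.70 with 5 of 7 called (7 adjusted over the list alone). In the list of cranial transcription factors (median 0.53), Irx2 (1.87) and Foxa2 (1.57) were higher while Ebf1 (-1.22) was lower; with a filter of 60% this list had a median of 0.10 and adjusted p = 0.348, and with that filter it passed in no regional comparison. Synaptic genes were higher at a median of 0.32, with Syt1, the calcium sensor of transmitter release, at 1.36 and the vesicle protein gene Vamp2 at 1.03; 12 of 22 were called higher and 1 lower (13 and 1 adjusted over the list alone). Glutamate receptor genes had a median of 0.53, with Gria1 at 0.75 and Gria2 at 0.70, but adjusted p = 0.0947 with an estimated correlation. Sodium and calcium channel genes had a median of 0.51, with Scn3b at 1.04 and Scn2a at 1.05, and adjusted p = 0.0825 with an estimated correlation and 0.0817 with that filter.

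Glial and connective tissue genes were lower in the oculomotor samples at 6 weeks. The meningeal and fibroblast list had a median of -1.50 (adjusted p = 1.71e-21) with 16 of 16 measured genes called lower and 16 adjusted over the list alone, among them Col3a1 (-2.77), Ogn (-2.72) and Igfbp4 (-1.49). Reactive astrocyte genes had a median of -1.09, with the filament genes Gfap at -2.25 ± 0.21 and Vim at -1.59, and astrocyte genes one of -0.13, with Aqp4, the water channel, at -0.92. The oligodendrocyte list had a median of -0.44 with 17 of 30 called lower (19 adjusted over the list alone), including Gsn (-1.48), Gjb1 (-1.14) and Ugt8a, which makes a myelin lipid (-0.86). The microglia and macrophage list had a median of -0.47 with 15 of 24 called lower (16 adjusted over the list alone), including C1qb (-0.84) and Csf1r (-0.58), the receptor on which microglia depend. Cholesterol synthesis genes had a median of -0.62, with Hmgcs1 and Sqle both at -0.90, and 11 of 18 called lower (12 adjusted over the list alone). Of the motor neuron and cholinergic list (median -0.71), 9 of 15 genes were called lower (9 adjusted over the list alone), among them Nefh (-1.14), which builds neurofilaments. Of 2 probe sets of Prph, another filament gene, one was lower (-2.35) and the other higher (0.55). Glycinergic genes were lower at a median of -0.40, with the receptor gene Glra1 at -1.47. The growth factor gene Igf1 had -1.40 and Fgf1 -0.84, while the neurotrophic list as a whole had a median of -0.02 and adjusted p = 0.127 with an estimated correlation. Sod1, which is mutated in some familial ALS, differed by 0.32 ± 0.12 (adjusted p = 0.0612). Its probe set is one for the mouse gene, and the labels name no mutation. Sod1 values here and below therefore do not show the level of a mutated form.

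In control mice of 10 weeks the same neuron classes set the regions apart, which shows the difference without the disease. Slc6a3 was higher in the oculomotor nucleus by 3.45 ± 0.19 and Nr4a2, a transcription factor of dopamine neurons, by 1.93. Slc6a4 was higher (adjusted p = 3.16e-12) over a spinal cord signal below the offset, at 5.31, or 3.65 with an offset 4 times larger. Hoxc8 was lower at -4.84 (-3.67 with the larger offset), and Slc18a3 at -1.88 and Chodl at -2.08 were lower as at 6 weeks. Myelin genes were lower: 25 of 30 oligodendrocyte genes were called lower in the oculomotor nucleus (26 adjusted over the list alone), with a median of -0.70 and adjusted p = 5.26e-24.

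The growth hormone gene Gh was also called higher (adjusted p = 0.0238), with signals of 427.8, 773 and 2934 in the control oculomotor arrays and 15.5, below the offset, in both control spinal cord arrays. The size of its change was 4.66 ± 1.32 with the offset used and 3.27 with one 4 times larger. Growth hormone is made in the pituitary, and replicate 3 of this oculomotor group also had a signal of 3008 for prolactin (Prl), against at most 305 on arrays without high hormone signals. Without oculomotor replicate 3 the adjusted p of Gh was 0.0864, without spinal cord replicate 2 or 3 it was 0.133 or 0.104, and with the larger offset it was 0.0642. The remaining named rises were Tcf7l2 (3.00 ± 0.20), Ddc (2.85 ± 0.17), Cartpt (2.75 ± 0.17), Th (2.72 ± 0.14) and Irx2 (2.07 ± 0.17). The remaining falls were Hoxd8 (-4.09 ± 0.18), Hoxb6 (-4.07 ± 0.24), Aplnr (-4.06 ± 0.21), Serpinb1b (-3.73 ± 0.25), Hoxa5 (-3.40 ± 0.41), Hoxb5 (-3.30 ± 0.28) and Prph (-2.67 ± 0.22, with its other probe set at -0.09). In total 1841 probe sets of 1411 genes were called, 899 higher and 942 lower, and 269 of them changed at least 2-fold (121 higher and 148 lower). Without spinal cord replicate 2 the count was 875.

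Of the 42 lists, 25 passed in control mice, 7 higher and 18 lower, and 13 also with an estimated correlation. The dopaminergic list had a median of 1.39 (10 of 11 called higher, 10 adjusted over the list alone) and the serotonergic list one of 0.71 (4 of 7 called higher and 1 lower, 5 and 1 adjusted over the list alone). Receptor genes for GABA were higher, with Gabrb2 at 1.39, Gabrg1 at 0.90 and Gabrb1 at 0.74, and that list had adjusted p = 0.0927 with an estimated correlation. Syt1 (1.62) and Scn3b (1.48) were higher, though the synaptic and channel lists reached adjusted p = 0.109 and 0.0927 with an estimated correlation. Meningeal genes (median -1.21), reactive astrocyte genes (median -0.73, Gfap -2.05) and cholesterol synthesis genes (median -0.37) were lower. Microglial genes were lower at a median of -0.43, with Csf1r at -0.65 and the microglial adaptor Tyrobp at -0.60. Genes of antigen presentation had a median of -0.22, with Cd74 at -0.78 and adjusted p = 0.270 with an estimated correlation. Respiratory chain genes had a median of -0.09 and adjusted p = 0.576 with an estimated correlation. The antioxidant Gpx3 was higher (1.30), against a list median of -0.12 and adjusted p = 0.119 with an estimated correlation. Sod1 differed by -0.12 ± 0.13 (adjusted p = 0.611).

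In mutant mice of 10 weeks, genes of monoamine neurons were again higher in the oculomotor nucleus, and microglial genes were lower there. Slc6a4 was higher (adjusted p = 4.77e-14) over a spinal cord signal below the offset, at 5.99, or 4.39 with an offset 4 times larger. Ddc was higher by 3.14 ± 0.15, Cartpt by 3.07 ± 0.15, Slc6a3 by 2.80 ± 0.17 and Th by 2.53 ± 0.13. Hoxc8 was lower at -5.23 (-3.88 with the larger offset). Of the 24 measured microglia and macrophage genes 19 were called lower in the oculomotor nucleus (20 adjusted over the list alone), with a median of -0.70 and adjusted p = 3.46e-12. Among them were Tyrobp (-1.11 ± 0.14), C1qa (-0.95), C1qb (-0.90) and Csf1r (-0.81 ± 0.10).

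Tcf7l2 (2.12 ± 0.18) and Slc7a3 (2.11 ± 0.16) were among the largest rises, and Hoxd8 (-4.52 ± 0.16), Hoxb5 (-3.97 ± 0.25), Hoxa5 (-3.91 ± 0.36), Hoxb6 (-3.58 ± 0.22), Aplnr (-3.56 ± 0.19), Tac2 (-3.54 ± 0.33) and Serpinb1b (-3.44 ± 0.22) among the largest falls. Gh had 4.12 ± 1.18 (adjusted p = 0.0197), with a signal of 13207 on oculomotor replicate 2, where Prl stood at 2209, and 120.5 and 332.5 on the other 2 arrays. Without that array the Gh value was 2.17 (adjusted p = 0.104), and without spinal cord replicate 1 or 3 the adjusted p was 0.0546 or 0.0574. In total 2619 probe sets of 1988 genes were called, 1263 higher and 1356 lower, and 267 changed at least 2-fold (115 higher and 152 lower).

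Here 19 of 42 lists passed, 7 higher and 12 lower, and 14 of them also with an estimated correlation. The oligodendrocyte list (median -0.53, 22 of 30 lower, 24 adjusted over the list alone), the meningeal list (median -1.03, 16 of 16) and the cholesterol list (median -0.33, 8 of 18 lower, 10 adjusted over the list alone) were lower. Disease-associated microglia genes were lower at a median of -0.43, with 12 of 19 called and 12 adjusted over the list alone. Gfap (-2.32), Prph (-2.96, with its other probe set at -0.10), Slc18a3 (-1.56) and Chodl (-2.17) were lower, and Syt1 (1.60) and Scn3b (1.74) higher. The channel list had a median of 0.35 and adjusted p = 0.0311 with an estimated correlation, and the synaptic list a median of 0.23 and adjusted p = 0.142 with an estimated correlation. Circadian genes had a median of 0.12, with Per1 at 0.69, Hlf at 0.58 and Csnk1e at 0.38, but adjusted p = 0.216 with an estimated correlation and, without oculomotor replicate 1, 0.136. Sod1 differed by 0.12 ± 0.12 (adjusted p = 0.515).

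**Figure D2:**
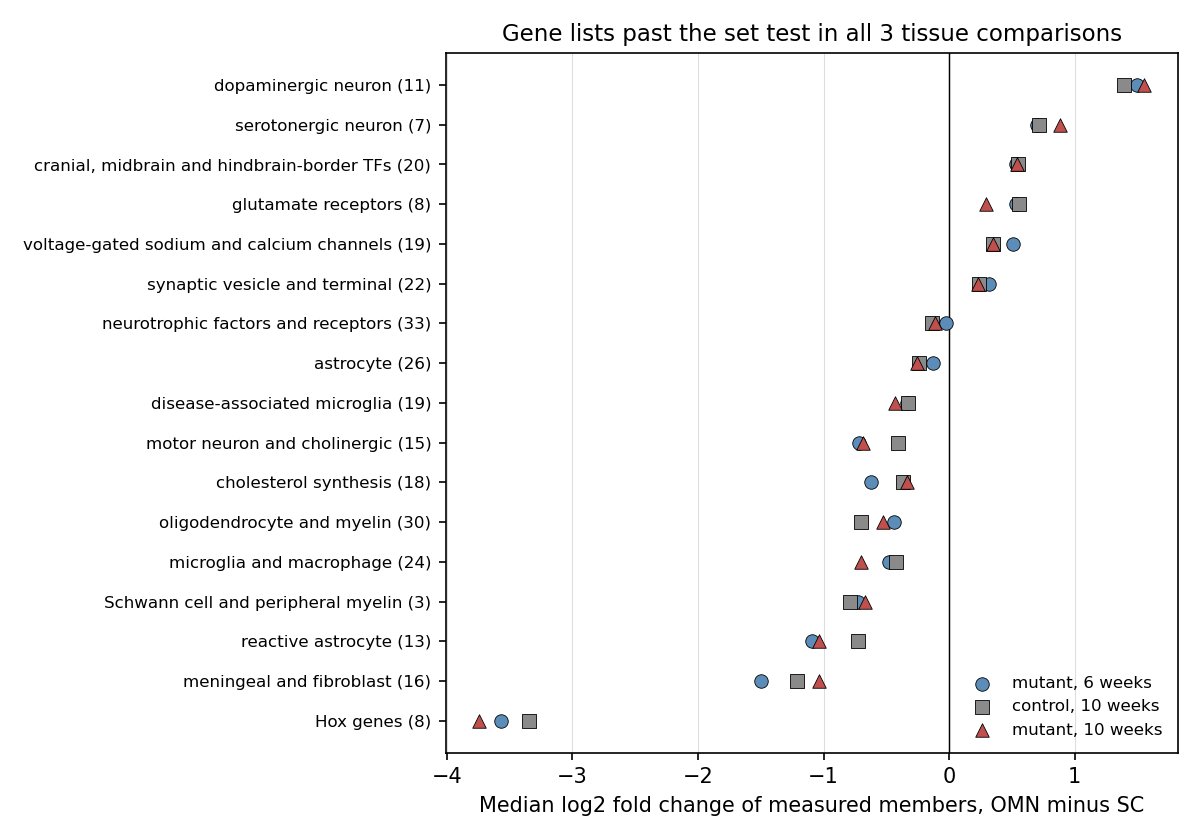
Median log2 fold change, oculomotor nucleus minus spinal cord (x axis), of the measured members of each gene list that passed the set test in all 3 tissue comparisons (y axis, number of measured members in brackets), with a circle for mutants of 6 weeks, a square for controls and a triangle for mutants of 10 weeks. The Hox medians lie at -3.57, -3.35 and -3.74, and the dopaminergic medians at 1.50, 1.39 and 1.55.

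The regional differences recurred across ages and genotypes. Averaged over the 3 conditions, Slc6a3 was higher in the oculomotor nucleus by 3.31 ± 0.10, while Hoxd8 stood at -4.11 ± 0.10 and Tac2 at -2.81 ± 0.20. For genes with a group below the offset the size depends on it: Slc6a4 had 5.34, Gh 3.28 and Hoxc8 -5.08, and 3.75, 2.43 and -3.81 with an offset 4 times larger. In all 3 comparisons and in 1 direction, 1014 probe sets were called, 417 higher and 597 lower in the oculomotor nucleus, and 150 of them changed at least 2-fold in all 3 (56 higher and 94 lower). Of 483 called with a 2-fold change in at least 1 comparison, 467 had 1 sign in all 3. Controls and mutants of 10 weeks shared 559 higher and 716 lower calls, against 83.6 and 94.1 by chance, and 1 probe set was called in opposite directions. Across probe sets, which are not independent, the fold changes of these 2 comparisons correlated at r = 0.776. Set against mutants of 6 weeks, likeness was lower: r = 0.716 with 7 opposite calls for controls, and r = 0.696 with 18 for mutants of 10 weeks. The mean contrast called 5121 probe sets, 2715 higher and 2406 lower, and 22 lists, 15 of them also with an estimated correlation. Sod1 had 0.11 ± 0.07 (adjusted p = 0.264).

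Between mutant and control oculomotor nucleus at 10 weeks, the comparison that asks how mutants differ from controls in the spared region, the nuclear noncoding RNA Malat1 rose most and the neuropeptide gene Tac2 fell most. Malat1 was higher in mutants by 4.63 ± 0.47 (24.8-fold, adjusted p = 1.05e-04), from a control mean of 7.78 ± 0.53 (SD) to 12.41 ± 0.56 on the log2 scale. The microtubule gene Map1b rose by 1.63 ± 0.27, the anchoring protein gene Akap9 by 1.39 ± 0.21, the kinase gene Wnk1 by 1.38 ± 0.24 and the ubiquitin ligase gene Cbl by 1.25 ± 0.15. Tac2 fell by 1.78 ± 0.33 (adjusted p = 0.0104), and Lrrtm1, which organises synapses, fell by 1.07 ± 0.19 (adjusted p = 0.00734). Slc6a4 was higher in mutants by 0.82 ± 0.17 (adjusted p = 0.0212).

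Other rises were Max, the partner of Myc (1.57 ± 0.33), Ubxn2a (1.52 ± 0.24) and Commd1, which acts in copper handling (1.23 ± 0.18). In total 200 probe sets of 154 genes were called, 141 higher and 59 lower in mutants, and 30 changed at least 2-fold, 28 of them upward. The probe sets of a gene did not move alike: the 5 of Malat1 ran from 0.37 to 4.63 with 3 called higher, the 3 of Map1b from -0.28 to 1.63 with 1 called, those of Ubxn2a from -0.01 to 1.52 and those of Wnk1 from -0.05 to 1.38, while both of Cbl were called (0.98 and 1.25). The other probe set of Lrrtm1 had -0.53 and was not called. Leaving out single arrays gave 47 (without mutant oculomotor replicate 1) to 341 calls (without mutant spinal cord replicate 1 of 10 weeks), and leaving out both arrays with high pituitary hormone signals, a setting chosen after seeing the data, gave 57. Slc6a4 then had an adjusted p of 0.256 and Max 0.0788; without single oculomotor arrays of 10 weeks Slc6a4 reached 0.117 (mutant replicate 2), Max 0.104 (mutant replicate 1) and Tac2 0.0656 (control replicate 1).

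Of the lists, 3 passed here and none of them with an estimated correlation. All 7 serotonergic genes were higher in mutants, at a median of 0.36 (adjusted p = 4.77e-04, and adjusted p = 0.249 with an estimated correlation), with 1 called and 5 adjusted over the list alone; Gata2 had 0.52 and Ddc 0.50. Respiratory chain genes were higher at a median of 0.06, 54 of 69 of them (adjusted p = 4.77e-04, and adjusted p = 0.849 with an estimated correlation), with 1 called and 4 adjusted over the list alone, but with quantile normalization their median was -0.02, and without mutant replicate 2 the adjusted p was 0.397. Of these, Uqcrfs1 had 0.54 (adjusted p = 0.0425) and Atp5g3 0.36 (adjusted p = 0.0517). Oligodendrocyte genes had a median of 0.12, with Cnp at 0.52 and Mbp at 0.53, adjusted p = 0.651 with an estimated correlation and 0.201 without control replicate 2; 1 was called, 2 adjusted over the list alone. Sod1 had 0.25 ± 0.12 (adjusted p = 0.340).

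**Figure D3:**
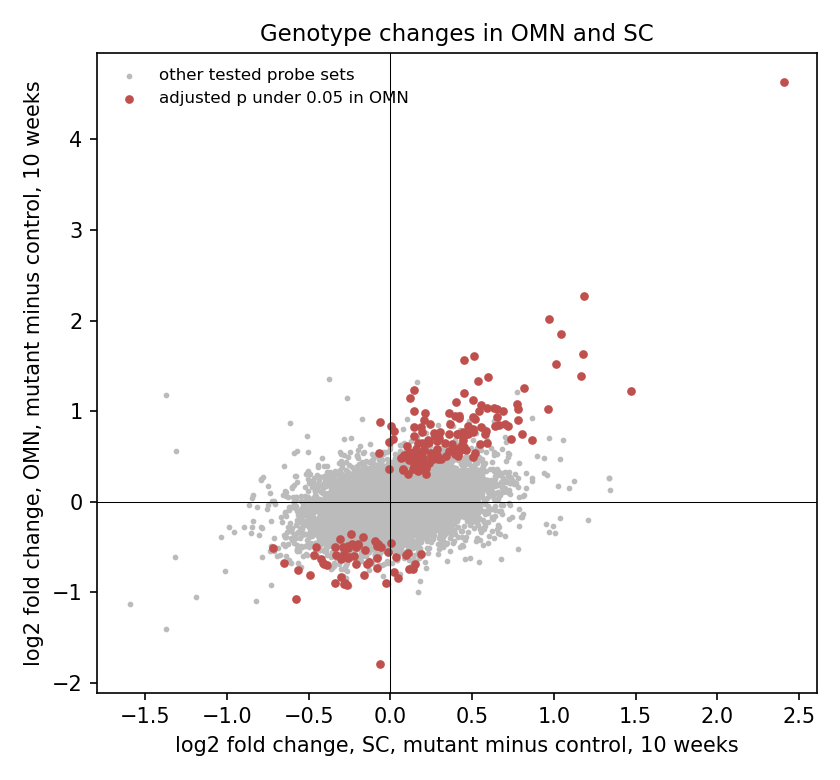
Log2 fold change of mutant over control at 10 weeks in spinal cord (x axis) and in oculomotor nucleus (y axis), a point per tested probe set, with the 200 called in the oculomotor nucleus in red and the others in grey. Of the 200, 186 have the same sign in spinal cord.

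In spinal cord, the affected region, mutants of 10 weeks had higher levels of microglial genes than controls, although no single member of the list was called. All 24 measured microglia and macrophage genes were higher, at a median of 0.28 (adjusted p = 2.80e-07, and adjusted p = 0.134 with an estimated correlation), 4 of them adjusted over the list alone. Cx3cr1, the microglial fractalkine receptor, had 0.97 ± 0.18 (adjusted p = 0.0881), the Fc receptor gene Fcgr3 0.64 (adjusted p = 0.261) and the complement genes C1qb 0.49 (adjusted p = 0.235) and C1qc 0.46 (adjusted p = 0.270). Commd1 was higher in mutants by 1.47 ± 0.20 (2.77-fold, adjusted p = 0.00717), the ubiquitin ligase gene Pja2 by 0.81 ± 0.12 (adjusted p = 0.0130), and the RNA-binding protein gene Celf4 was lower at -0.72 ± 0.12 (adjusted p = 0.0330).

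These 3 probe sets of 3 genes were the only ones called, 2 higher and 1 lower (2 and 0 with quantile normalization), and other probe sets of Pja2 and Celf4 had -0.65 and -0.05. None was called without control replicate 2, without control replicate 3 or without mutant replicate 2 of spinal cord, while 51 were called without mutant replicate 1; the number called at an unadjusted p under 0.05 in limma was 1595, against 679 by chance. The next smallest p-values belonged to Map3k7 (0.74), Yipf1 (0.82), Atox1, a copper chaperone gene (-0.50), Nek4 (-0.71) and Farsb (-0.61), with adjusted p from 0.0799 to 0.0944, and other probe sets of Atox1 and Farsb reached 0.20 and 0.03. Disease-associated microglia genes were higher, 16 of 19, at a median of 0.16 (adjusted p = 0.650 with an estimated correlation), with Fth1 at 0.38 and Grn at 0.27, and meningeal genes lower, 15 of 16, at a median of -0.14 (adjusted p = 0.823 with an estimated correlation), with Mgp at -0.54 and Dcn at -0.43; 0 members of either were called, and 0 adjusted over the list alone. The former list had an adjusted p of 0.324 without control replicate 3 and 0.202 without mutant replicate 1, the latter one of 0.396 without mutant replicate 3. Sod1 had 0.00 ± 0.13 (adjusted p = 0.992).

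**Figure D4:**
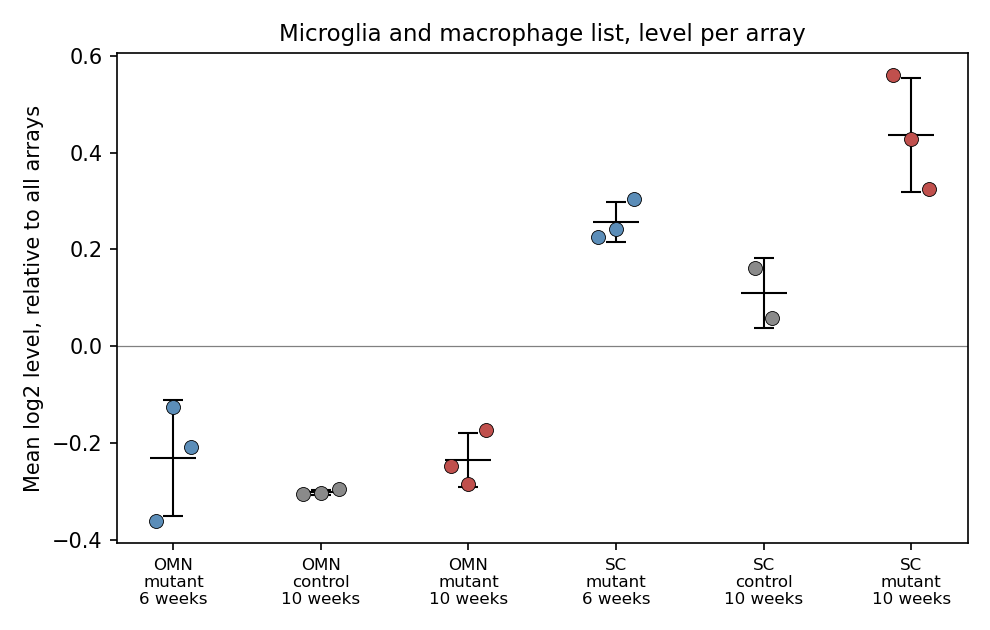
Mean log2 level of the microglia and macrophage list on each array, relative to the mean of all arrays (y axis), by group (x axis), with bars for the group mean and error bars for the SD. The control spinal cord arrays lie at 0.0586 and 0.162, the mutant ones of 10 weeks between 0.325 and 0.560, and the oculomotor arrays below 0.

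Averaged over the 2 regions at 10 weeks, a mean that does not need a change in each, Malat1 was higher in mutants by 3.52 ± 0.35 (11.5-fold, adjusted p = 4.07e-05), Map1b by 1.40 ± 0.20, Commd1 by 1.35 ± 0.13, Akap9 by 1.28 ± 0.16, Ubxn2a by 1.27 ± 0.18, Cbl by 1.04 ± 0.11 and Max by 1.01 ± 0.25. Cx3cr1 was higher by 0.99 ± 0.12 (adjusted p = 2.64e-04), while the actin regulator gene Cap1 (-1.36 ± 0.36, adjusted p = 0.0461) and Nell2 (-1.12 ± 0.28, adjusted p = 0.0380) were lower. Of these genes Commd1 alone was called in both regions; in spinal cord Malat1 had 2.41 (adjusted p = 0.0992) and Max 0.45 (adjusted p = 0.676). Other probe sets of Nell2, Map1b and Ubxn2a had -0.40, -0.54 and -0.10. The mean contrast called 436 probe sets of 350 genes, 278 higher and 158 lower, or 217 and 221 with median centring. Of the 200 oculomotor calls, 186 (93%) had the same sign in spinal cord and 95 had it at an unadjusted p under 0.05 in limma. The 3 probe sets called in spinal cord were also called in the oculomotor nucleus, 2 higher and 1 lower in both. This holds for single probe sets: of the 3 of Pja2, 1 was called higher (0.75) and 2 lower (to -0.89) in mutant oculomotor nucleus. The serotonergic list (median 0.36, adjusted p = 0.410 with an estimated correlation; 2 called, 4 adjusted over the list alone) and the microglia list (median 0.14, adjusted p = 0.410 with an estimated correlation; 1 called, 5 adjusted over the list alone) passed on average. The former did not pass in spinal cord alone (adjusted p = 0.436) nor on average with a filter of 60% (0.0703), and the latter did not pass in the oculomotor nucleus alone (0.620). Sod1 had 0.13 ± 0.09 (adjusted p = 0.471). The count was 92 without control spinal cord replicate 3 and 166 without both arrays with high pituitary hormone signals; Cap1 had an adjusted p of 0.181 and Nell2 of 0.164 without the former, and Max of 0.119 without control spinal cord replicate 2.

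The difference between mutants and controls was also compared between the 2 regions, where 2 lists and no single gene passed, and neither list with an estimated correlation. The genotype change in oculomotor nucleus minus that in spinal cord had a median of -0.26 over the 24 microglia and macrophage genes, negative in 22 of them (adjusted p = 9.26e-04, and adjusted p = 0.480 with an estimated correlation), with C1qa at -0.53 and Tyrobp at -0.51. Without control spinal cord replicate 3 the adjusted p of this list was 0.0929. The 69 respiratory chain genes had a median of 0.11, positive in 52 (adjusted p = 9.26e-04, and adjusted p = 0.783 with an estimated correlation), adjusted p = 0.634 with quantile normalization and 0.293 without mutant oculomotor replicate 2. No probe set was called in limma; 835 had an unadjusted p under 0.05, against 679 by chance, and 0 members of either list passed adjusted over the list alone. The values with the smallest p were those of Atox1 (0.71 ± 0.13) and Spata5 (-1.31 ± 0.25), each at an adjusted p of 0.391, followed by Proser1 (-1.01), Mpv17 (1.05), Tkfc (-1.08), Col6a2 (-0.91), Strn (-0.88), Atp6v1e1 (2.55 ± 0.63), Ece2 (0.71) and Mapre2 (0.82), and other probe sets of Atox1, Atp6v1e1 and Mapre2 had -0.15, -0.01 and as low as -0.29. Sod1 had 0.24 ± 0.18 (adjusted p = 0.850).

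In mutants, oculomotor samples of 10 weeks had higher Slc6a4 and Cartpt signals than those of 6 weeks. Myelin genes had lower signals as a list. The share of neighbouring tissue in each sample was not measured, so a change within the nucleus is not shown. Slc6a4 rose by 1.26 ± 0.17 (2.39-fold, adjusted p = 0.0118), Cartpt by 0.97 ± 0.15 (adjusted p = 0.0198) and the transporter gene Abca8a by 0.85 ± 0.13 (adjusted p = 0.0189). Of the 30 oligodendrocyte genes, 25 were lower at 10 weeks, at a median of -0.24 (adjusted p = 1.25e-13, and adjusted p = 0.0192 with an estimated correlation), with 0 called and 13 adjusted over the list alone, among them Ugt8a (-0.38) and Mal (-0.52). The mean level of this list, relative to all arrays, was -0.09 in mutants of 6 weeks and -0.32 in mutants of 10 weeks. In controls of 10 weeks it was -0.42, so a low level at 10 weeks was not particular to mutants. With no control of 6 weeks, age and disease stage were not separable here.

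No other probe set was called (3 higher and 0 lower; 10 and 4 with quantile normalization), against 1197 at an unadjusted p under 0.05 in limma. None was called without oculomotor replicate 2 of 6 or of 10 weeks, or without both arrays with high pituitary hormone signals, where Slc6a4 had an adjusted p of 0.105. Next by p were Tm4sf1 (0.81), Cd24a (0.66), Septin4 (-0.43), Hoxd8 (-0.89), Pth2 (-0.82), the kinase gene Prkcd (-1.32) and Dnajb11 (-0.72), at adjusted p from 0.0567 to 0.0776. The serotonergic list had a median of 0.39, with Ddc at 0.63 and Gch1 at 0.60 (adjusted p = 0.170 with an estimated correlation and 0.390 with a filter of 60%; 1 called, 4 adjusted over the list alone). Immediate early genes had a median of 0.15, with Fos at 0.87, Nr4a1 at 0.70, Egr1 at 0.66 and Ier3 at 0.57 (adjusted p = 0.529 with an estimated correlation and 0.205 without replicate 1 of 6 weeks; 0 called, 4 adjusted over the list alone). Respiratory chain genes had a median of -0.09 (adjusted p = 0.763 with an estimated correlation and 0.642 without replicate 3 of 6 weeks; 0 called, 0 adjusted over the list alone). Sod1 had -0.18 ± 0.12 (adjusted p = 0.699).

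In mutant spinal cord, several genes of connective tissue and of cholesterol synthesis fell between 6 and 10 weeks, but neither list passed with an estimated correlation (adjusted p = 0.257 with an estimated correlation for each). The smooth muscle actin Acta2 fell by 1.01 ± 0.14 (adjusted p = 0.00288), the collagen genes Col3a1 by 1.09 ± 0.17 (adjusted p = 0.00505) and Col1a1 by 1.12 ± 0.28 (adjusted p = 0.0395), and the matrix gene Ogn by 1.09 ± 0.25. Commd1 rose by 1.23 ± 0.18 (adjusted p = 0.00288), Rac3, a small GTPase of neurons, by 1.21 ± 0.20, and the neural transcription factor Myt1l by 1.14 ± 0.27. Msmo1, which acts in cholesterol synthesis, fell by 0.81 (adjusted p = 0.0233) and Hmgcs1, which feeds it, by 0.34 (adjusted p = 0.0325).

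Other rises were the noncoding RNAs Snhg11 (1.52 ± 0.28) and Rian (1.21 ± 0.20), Fmn2 (1.18 ± 0.27), Dop1b (1.13 ± 0.18) and Lix1 (1.12 ± 0.24), and Cald1, an actin-binding protein gene, fell by 1.16 ± 0.26, with another probe set at -0.27. Other probe sets of Rian (to -0.51), Fmn2 (to -0.21), Myt1l and Dop1b were not called. In total 374 probe sets of 311 genes were called, 242 higher and 132 lower; with median centring 129 were higher and 298 lower. At least 2-fold changes numbered 22, 16 of them upward. The count was 86 without spinal cord replicate 2 of 6 weeks and 122 without replicate 1 of 10 weeks; without the former Fmn2 had an adjusted p of 0.106, Myt1l of 0.0800, Msmo1 of 0.0997, Hmgcs1 of 0.114, Snhg11 of 0.0573 and Fdps of 0.0995, and without the latter Col1a1 of 0.148, Ogn of 0.119, Cald1 of 0.106, Lix1 of 0.0827 and Idi1 of 0.102. All 16 meningeal genes were lower, at a median of -0.38 (adjusted p = 2.03e-08, and adjusted p = 0.257 with an estimated correlation), 5 of them called and 9 adjusted over the list alone. Cholesterol genes had a median of -0.22 (adjusted p = 0.257 with an estimated correlation), with 5 of 18 called and 7 adjusted over the list alone, among them Idi1 (-0.54) and Fdps (-0.48). Microglial genes were higher, 21 of 24, at a median of 0.21 (adjusted p = 0.0487, and adjusted p = 0.559 with an estimated correlation), with Fcgr3 at 0.51, Rac2 at 0.48 and C1qa at 0.40, 0 called and 0 adjusted over the list alone; without spinal cord replicate 1 of 10 weeks the list had an adjusted p of 0.394. Across probe sets the age changes of the 2 regions correlated at r = -0.02, and 199 of the 374 spinal cord calls (53.2%) had the same sign in the oculomotor nucleus. Sod1 had 0.02 ± 0.12 (adjusted p = 0.959).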

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

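The tests of the unused array, of the 6-week mutants, of the spike signals and of meningeal, blood and vessel genes were chosen after the result was seen. The genotype change differed between the regions, by limma's set test of the difference, for the microglia and macrophage list (median -0.26, oculomotor nucleus minus spinal cord) and for the respiratory chain and ATP synthase list (median 0.11). Neither passed with an estimated correlation (adjusted p = 0.480 and 0.783), and the former did not pass without control spinal cord replicate 3 (0.0929). Control transcripts, which no comparison uses, differed on 2 arrays. The Dap transcript had a signal of 2693 on mutant spinal cord replicate 1 of 10 weeks, against at most 15.8 on the other arrays used, and no explanation was tested for it. Without this array, genotype gave 51 calls in spinal cord and 341 in the oculomotor nucleus, against 3 and 200 with it. The older Cre probe set had 76601 on control spinal cord replicate 1, the array left out, against 6042 to 14261 on the arrays used.

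The array left out, control spinal cord replicate 1, had signals that correlated with those of no other array. The signals of an ordinary array in another order are argued against by its 5th percentile of 47, against 6.2 to 9.1 on the 17 arrays used. A weak hybridisation of this array design is argued against by the ratio of the newer to the older Cre probe set, 0.0175 against 1.20 to 2.57. Another array design read under these probe set names stays open: the older Cre probe set lay above 99.996% of the array's probe sets, which does not decide it. No biological explanation was tested, since the values are not tied to genes.

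The 200 probe sets called between mutant and control oculomotor nucleus at 10 weeks were weighed as the second pattern. For 92.5% of them (185) the 6-week oculomotor mutants lay nearer to the 10-week mutants than to the 10-week controls (for 70.5%, or 141, in spinal cord). This argues against a change within the mutants between 6 and 10 weeks as the cause of most, though Slc6a4 is an exception (means 9.88, 11.14 and 10.31). With no control of 6 weeks, the values cannot tell whether the genotypes already differed at that age. Other probe sets of the same genes moved by a median of 0.208 of the called change (127 probe sets, quartiles -0.06 and 0.51), against 0.798 for regional calls of matched t, so part of the signal may belong to single probe sets and not to whole transcripts. The newer Cre spike was 1.60 times higher in the 10-week oculomotor mutants than in their controls (at least 15977 against at most 12884), which goes with a difference in handling. The 6-week oculomotor mutants had 19246 to 20524, also above the controls, so a difference in handling could give the 92.5% too. In spinal cord the controls had 10771 and 14319, the mutants of 6 weeks 12107 to 14559, overlapping them with a Malat1 mean of 11.16 against 8.34, and the mutants of 10 weeks 12699, 19597 and 16436. Of these last 3 arrays the first also had the lowest Malat1 signal (719.7, against 2115 and 3171), so the spike does not decide it. That array is also the one with the high Dap signal. A difference in handling, for which the labels give no batch, and a genotype difference from before 6 weeks both stay open.

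The higher microglia and macrophage list in mutant spinal cord at 10 weeks was weighed as the third pattern. A single array is argued against by the lowest median without any array of the groups, 0.191 (highest adjusted p = 9.84e-04). The scaling of the arrays is argued against by the lower median under quantile normalization and median centring, 0.230. More meningeal, blood or vessel tissue in the mutant samples stays open. The medians of those lists were -0.14, -0.28 and -0.07, lower and not higher, but the levels of control and mutant arrays overlapped for each of the 3 lists, and the meningeal list did not pass with quantile normalization (adjusted p = 0.0899), median centring (0.0576) or an estimated correlation (0.823). The blood cell list held only 2 measured genes. Handling, the 2 control arrays and a response to the genotype stay open too, and the latter was not tested further. With an estimated correlation the adjusted p of the microglia and macrophage list was 0.134.

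Other splits of the same arrays were counted for 8 of the 10 contrasts, those with at least 3 arrays in each group or over several groups; regions of controls and genotype in spinal cord, with 2 control arrays, were left out. For the mean genotype contrast, 1 of 100 splits, the real one, gave as many (436 against at most 13). For the mean regional contrast, 1 of 100 gave as many (5121 against at most 2686, in a split that relabels 2 of the 6 arrays of 6 weeks only). Both shares lie under 0.05 if the arrays are separate samples. They do not exclude chance, since the labels do not say that the arrays are separate animals. Splits that mix groups also move real differences into the spread, which can lower their counts. For the genotype by region difference all 100 gave as many as the 0 called, which any split must, so this count decides nothing. The highest other split called 446. It swaps the genotype of all 6 oculomotor arrays and of 2 spinal cord arrays, so it still holds the oculomotor genotype difference with its sign turned. The cause of its count was not tested. Contrasts of 3 against 3 arrays make 10 splits, too few for a share under 0.05. There 1 split, the real one, gave as many: 3239 against at most 0 for regions at 6 weeks, 2619 against 1 for regions of mutants at 10 weeks, 200 against 1 for genotype in the oculomotor nucleus, 3 against 2 for age in the oculomotor nucleus and 374 against 2 for age in spinal cord.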

How the results depend on the processing

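The fit of all 18 arrays and the fit without both arrays with high pituitary hormone signals were chosen after the data were seen. Of 161 named gene results past the threshold, 156 kept direction and call with quantile normalization, 160 with median centring, 160 with values floored at the offset, 160 with an offset 4 times larger, 147 with no filter, 154 without a trend and 142 with the arrays of a contrast alone; of 104 list calls, 96, 102, 102, 104, 99, 104 and 103 did. With a filter of 60% all 100 genes left kept their call, and 23 of 100 lists lost theirs. Fewer genes were tested there, and list members of low signal were left out. When probe sets of low signal were tested too, 14 genes and 5 lists lost their call. Leaving out an array ended the call of 31 genes and 19 lists at least once. The causes of these losses were not tested. Genes were named for large changes or small p-values, which favours keeping a call. These shares therefore do not describe all called probe sets.

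Counts of called probe sets moved by more than 1.5 times in these settings. With quantile normalization the age contrast of the oculomotor nucleus gave 14, with floored values 6 and with a larger offset 11. With no filter, genotype gave 118 in the oculomotor nucleus, 5 in spinal cord and 288 on average, and age 5 in the oculomotor nucleus. Without a trend, genotype in spinal cord gave 1 and age in the oculomotor nucleus 7. With the arrays of a contrast alone, genotype gave 392 in the oculomotor nucleus and 1 in spinal cord, and age 0 and 42 in those regions. With 1 probe set per gene, which tests fewer, the regional contrast gave 2123 at 6 weeks and 3241 on average, genotype 62 in the oculomotor nucleus, 5 in spinal cord and 183 on average, and age 10 and 237. The pairwise rule gave 407, 332 and 328 for the regions (6 weeks, controls, mutants of 10 weeks), 46 and 27 for genotype (oculomotor nucleus, spinal cord) and 10 and 37 for age. The 2-fold threshold, which is stricter, gave 338, 269, 267 and 234 (mean) for the regions, 30, 1 and 13 (mean) for genotype and 1 and 22 for age. Without both hormone arrays, genotype gave 57 in the oculomotor nucleus and 166 on average, and age in the oculomotor nucleus 0. The genotype by region difference gave 0 in every setting run, with 835 at an unadjusted p under 0.05 in limma as reported.

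With all 18 arrays, whose added array does not follow the probe sets, the regions gave 310, 314, 209 and 1354 (mean), genotype 1, 0 and 1 (mean), and age 0 and 0. Of 161 named gene results 76 kept their call in that fit, and of 104 list calls 71 did. The set test of the microglia and macrophage list for genotype in spinal cord gave an adjusted p of 0.154. There the control regional medians of these lists reversed: antioxidant 0.60, astrocyte 0.30, cholesterol 0.14, disease-associated microglia 0.21, glycinergic 0.0921, neurotrophic 0.0902, oligodendrocyte 0.24, respiratory chain 1.01 and Schwann cell 0.26, and the genotype by region median of the respiratory chain became -0.98. Atox1 reversed to 0.48 for genotype in spinal cord and -0.27 for the difference, and Sod1 to 0.68 for the control regions and -0.55 for the difference. In other settings Sod1, which passed in no contrast, changed sign for genotype in spinal cord (-0.0656 with quantile normalization, -0.0472 with median centring, and -0.0803 to 0.153 without single arrays, negative without control replicate 3 or mutant replicate 2 or 3), for age in spinal cord (-0.0571, -0.0635, and -0.0685 to 0.165, negative without replicate 3 of 6 weeks or replicate 2 or 3 of 10 weeks) and for the regions of 10-week mutants (-0.0274 without mutant spinal cord replicate 1). The respiratory chain median for genotype in the oculomotor nucleus was -0.0178 with quantile normalization, and the blood cell median at 6 weeks 0.12 with no filter.

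The labels do not say whether equal replicate numbers stand for the same mice. Residuals of 8 same-number pairs across regions correlated at -0.07 to 0.13, so the numbers were not taken as pairs. The 16 same-number pairs within a region correlated at -0.10 to 0.11, but they join different genotypes or ages and so cannot be the same mice. Xist was high on control replicate 3 of both regions (496 and 561), which leaves shared mice open. The replicate block joined equal numbers across regions for the regional contrasts and the genotype by region difference. For genotype and age it joined them within a region, where it says nothing about shared mice. With this block the control regional contrast gave 1211, genotype in spinal cord 0 (Commd1 and Pja2 at an adjusted p of 0.0572, Celf4 at 0.0916) and age in the oculomotor nucleus 5. Of the calls, 157 of 161 genes and 102 of 104 lists were kept. The lists lost in the set test were disease-associated microglia for genotype in spinal cord (adjusted p = 0.0686) and microglia and macrophage for age there (0.0529).

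Leaving out each array gave 2532 to 3381 calls for the regions at 6 weeks, 875 (without control spinal cord replicate 2) to 1972 for controls, 1804 to 2754 for mutants of 10 weeks and 4476 to 5090 for their mean; a lone array left in a group is assumed to vary like the other groups. Genotype in the oculomotor nucleus gave 47 to 341: 57, 91 and 103 without control replicates 1, 2 and 3, 47, 109 and 93 without mutant replicates 1, 2 and 3, and 341 without mutant spinal cord replicate 1. Genotype in spinal cord gave 0 to 51: 0 without control replicate 2 or 3 or mutant replicate 2, 51 and 1 without mutant replicates 1 and 3, and 5 without replicate 1 of 6 weeks. The mean genotype contrast gave 92 to 644: 201 and 244 without control oculomotor replicates 1 and 3, 271 and 92 without control spinal cord replicates 2 and 3, 238, 221 and 270 without mutant oculomotor replicates 1, 2 and 3, and 251 and 220 without mutant spinal cord replicates 2 and 3. Age in the oculomotor nucleus gave 0 to 6: 0 and 6 without replicates 2 and 3 of 6 weeks, 0 without replicate 2 of 10 weeks, 5 without control replicate 2 and 5 without spinal cord replicate 2 of 6 weeks. Age in spinal cord gave 86 to 451: 115, 86 and 194 without replicates 1, 2 and 3 of 6 weeks, and 122 and 224 without replicates 1 and 3 of 10 weeks. The genotype by region difference gave 0 to 0.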

Other observations

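No tests are reported here, and these values were looked at after the data were seen. Pituitary hormone genes had high signals on 2 oculomotor arrays. Mutant replicate 2 of 10 weeks had 13207 for Gh, 6756 for Pomc, 2209 for Prl and 1134 for Cga, and control replicate 3 had 2934 for Gh and 3008 for Prl. On the other arrays used Gh lay between 10.6 and 1045, Pomc between 106 and 382, Prl between 8.3 and 305 and Cga between 10.7 and 186.

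A probe set of Xist, which is expressed from the inactive X chromosome, had signals of 496 on control oculomotor replicate 3 and 561 on control spinal cord replicate 3, and between 124 and 241 on the other arrays used. The labels do not give the sex of the mice.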
